A study of Mus musculus with 12 samples.

How the data were processed

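Poly(A)-selected RNA from hearts of C57BL/6J mice, an inbred laboratory strain, was analysed in 12 libraries. The labels place the libraries in 4 groups of 3: females at 4 months, females at 20 months, males at 4 months and males at 20 months. Per the labels' protocols, RNA was purified with a Zymo Direct-zol kit and poly(A) RNA was captured on oligo-dT beads. Libraries were made with an NEBNext Ultra II kit that keeps no strand information, and sequencing was done on a NovaSeq 6000. Because the kit does not mark strand, reads of a gene and of an overlapping antisense gene cannot be told apart.

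The submitters' processing notes name STAR 2.7.6, StringTie 2.1.1 and the genome build GRCm39, without their roles or order. The annotation release, read trimming and read length are not given in the sources used here. The deposited table holds estimated counts per gene, not scaled between libraries, and it pairs each Ensembl gene ID with a symbol. All values were whole numbers, so rounding the estimated counts changed none. Small values in the deposited table piled up at 4, with 11779 cells at 4 against 7904 at 3 and 5614 at 5. A unit of these estimated counts is therefore not taken as a read, and the totals are given as count units. Counts divided by 4 and rounded were tested as an added alternative. The annotation given with the data is GENCODE M21 on another build, so no coordinates are printed. It served only to place genes on autosomes, X or Y. It gave a chromosome for 24763 of the 24873 genes tested.

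Totals ran from 288297038 to 488255840 count units per library. From 24.3% to 31.4% of these fell on mitochondrially encoded genes. Another 5.64% to 7.26% fell on 6 nuclear gene models whose sequences resemble mitochondrial genes, where reads may be split between near-identical copies. On counts divided by 4 and rounded, replicate pairs within a group differed by 19.8 to 74.7 times the sampling variance per degree of freedom. These multiples depend on that divisor. No library was a copy of another. The labels give 3 libraries per group and do not say more of the animals, so p-values measure the spread between these libraries.

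Genes were tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood F test with robust estimation, TMM scaling, the filterByExpr filter and a model with a mean per group over all 12 libraries (8 residual degrees of freedom). Of the 53647 genes in the table, 24873 passed the filter. Of 7 contrasts, 4 compared pairs of groups, 2 averaged the age or sex effect over the other factor, and the last tested the difference between the age effects of the sexes. Age effects are 20 minus 4 months and sex effects male minus female. Adjusted p is the Benjamini-Hochberg value over the genes tested, with a threshold of 0.05, and all such p-values are two-sided. CPM values are counts relative to the TMM-scaled library size, and SE is the log2 fold change over the square root of the F statistic.

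Gene lists, 42 in number with 819 symbols of which 795 were tested, were fixed before the data were examined, as were the contrasts, the alternatives except those named as added, and the rule for named genes. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with the correlation estimated from the data. A list's members are also counted past 0.05 when adjusted over all genes and when adjusted over the list alone. By the rule, genes named in a contrast had an adjusted p under 0.05, a mean CPM of at least 1 in the higher group, a symbol that is not a predicted, clone or pseudogene name, and no overlap between the libraries compared. The 12 largest rises and the 12 largest falls were taken. The interaction was exempt from the overlap condition because fewer than 12 genes passed its test. List members were named by smallest adjusted p, 2 to 4 per list, and all X-inactivation and Y-linked list members were examined as label checks. Named beyond 4 per list were Ccl8 and Igfbp5 for age averaged over sexes, and Arntl for age and for sex averaged. Outside the rule, and after their values were seen, the atrial genes Myl7, Myl4 and Sln, the clock gene Dbp, and Nppb, Myh7, Col1a1, Col3a1 and Cdkn1a were named as well. Some genes that met the rule are not reported here, and counts of genes include them.

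The pipeline was tested on simulated counts drawn from the real means, library sizes and dispersions. In these, 200 genes with a mean CPM of at least 1 were changed. The rates of recovery do not cover genes of lower CPM. The edgeR test recovered 85.1% of genes changed 1.5-fold and 92.5% of those changed 2-fold for the age effect averaged over sexes (24064 genes run). For the age effect in females it recovered 61.2% and 86.6% (24011 genes), for that in males 58.2% and 89.6% (24041 genes), for the sex effect at 4 months 61.2% and 98.5% (23987 genes) and at 20 months 61.2% and 95.5% (24022 genes). For the sex effect averaged over ages it recovered 82.1% and 94.0% (24044 genes). For the interaction it recovered 19.4% and 65.7% (24065 genes). In these simulations a list of 50 genes raised 1.5-fold was called in each of the 7 contrasts, and 0 of 40 unmoved lists were called in any. The simulated genes were drawn independently of each other. The simulations therefore do not check the preset correlation for lists whose members move together.

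Alternatives fixed beforehand were DESeq2 (1.42.0) size factors within edgeR, no filter, a filter of CPM of at least 1 in 3 libraries, the DESeq2 Wald test, limma-voom, the replicate number as a block, leaving out each library in turn, annotated genes only, and fits on the 6 libraries compared. Added after seeing the data were counts divided by 4, a score for atrial transcripts as a covariate, a score for clock transcripts as a covariate, and a fit without 2 male libraries low in atrial transcripts. Leave-one-out runs for the correlations of effects were also added. Each score is the first principal component of the fixed atrial or circadian list over the 12 libraries.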

Results

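The series asks how age and sex shape gene expression in the mouse heart. Hearts of female and male mice at 4 and 20 months were measured, with 3 libraries in each of 4 groups and totals of 288297038 to 488255840 count units per library. The first principal component of log2 CPM held 14.7% of the variance and parted the ages. Its scores were above 0 in the 6 libraries of 20 months, up to 47.9, and from −55.6 to −4.32 in the 6 of 4 months. The labelled sexes were borne out in all 12 libraries. Xist, the RNA that coats the inactive X, stood at 362 ± 31.3 CPM in 4-month females and 343 ± 56.9 in 20-month females. It stood at 0.738 ± 0.395 and 0.610 ± 0.387 in males of those ages (SD, n = 3). The Y-linked helicase Ddx3y stood at 72.7 ± 3.66 and 68.5 ± 2.87 CPM in males of 4 and 20 months and at 0.0682 ± 0.0543 and 0.0508 ± 0.0462 in females (SD, n = 3).

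The first comparison asks what differed between 4 and 20 months when both sexes were weighed equally. The potassium channel gene Kcnk1 (ENSMUSG00000033998.10) rose most among the named genes, from 0.189 to 1.84 CPM in females and from 0.437 to 5.62 CPM in males, a log2 fold change of 3.49 ± 0.29 (SE). The noncoding RNA Snhg11 rose by a log2 fold change of 3.23 ± 0.34, and Scart1, a scavenger receptor gene, by 2.75 ± 0.18. Ddc (ENSMUSG00000020182.17), which encodes aromatic L-amino acid decarboxylase, fell from 3.60 to 0.784 CPM in females and from 2.97 to 0.586 CPM in males, a log2 fold change of −2.27 ± 0.29. Ighg2c, an immunoglobulin heavy-chain constant gene, rose from 2.08 ± 0.351 to 11.5 ± 2.04 CPM in females and from 2.75 ± 0.742 to 10.4 ± 0.539 in males (SD, n = 3). Reads of Ighg2c, and of Klk1b26 and Cyp2b10 below, may be shared with close relatives, which leaves the identity of the copy uncertain.

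Other genes that rose with age in all 6 older against all 6 younger libraries were Prom2 (log2 fold change 2.69), the kallikrein gene Klk1b26 (2.66), the cytochrome P450 gene Cyp2b10 (2.64), Vgll2, a cofactor of TEAD factors known from skeletal muscle (2.49), the cadherin gene Cdh22 (2.21), Ano5 (2.12) and the skeletal-muscle ryanodine receptor gene Ryr1 (1.96). Genes that fell in the same sense were Hrk, a pro-apoptotic BCL2-family gene (−1.08), Nrk (−0.98), Ccnjl (−0.75), Spsb4 (−0.70), Tox3 (−0.66), Grip2 (−0.62), Tceal8 (−0.52), Auts2 (−0.51), Ccdc69 (−0.44), Sec14l5 (−0.43) and Atp1b2, a beta subunit of the sodium-potassium ATPase (−0.42). Their adjusted p in edgeR's quasi-likelihood test ran from 2.33e-06 for Ighg2c to 0.0282 for Tox3.

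**Figure D1:**
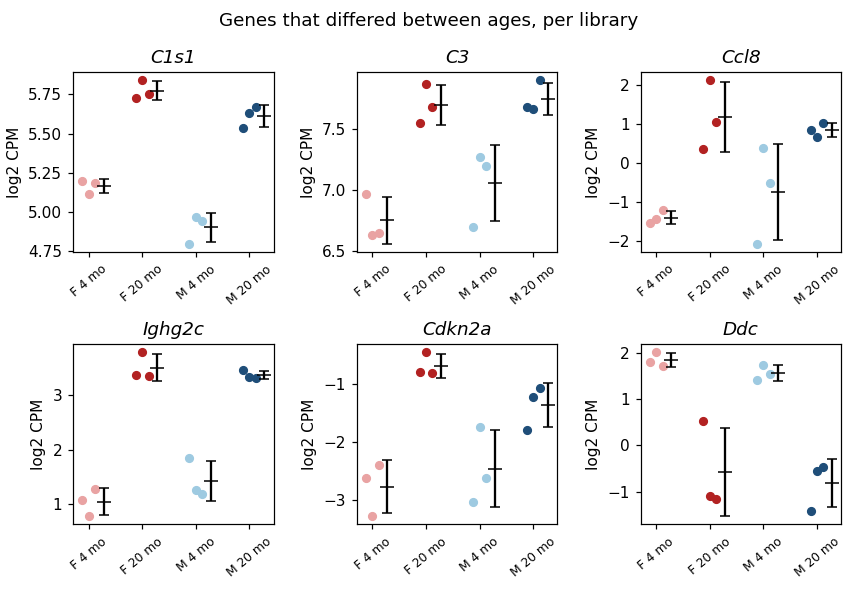
Log2 CPM of 6 genes (y axis) in each of the 12 libraries, grouped by sex and age (x axis; F, females; M, males). Points are libraries, and the bars beside them give the mean and SD of 3. C1s1, C3, Ighg2c, Ccl8 and Cdkn2a had higher means at 20 months in both sexes and Ddc a lower one; Ighg2c CPM averaged 2.08 and 11.5 in females of 4 and 20 months.

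Of 16 complement genes tested, 6 rose with age over all genes and 11 when adjusted over the list alone, and none fell. C1s1 rose by a log2 fold change of 0.66 (adjusted p = 6.12e-06), C1ra by 0.57, the alternative-pathway factor Cfb by 1.16 and the central component C3 by 0.81. C3 went from 108 ± 14.9 to 209 ± 23.5 CPM in females and from 135 ± 27.3 to 216 ± 20.3 in males (SD, n = 3), and reads of C1s1 and C1ra may be shared with their close copies. The camera test gave the complement list an adjusted p of 1.26e-11, and adjusted p = 0.279 with an estimated correlation. Fibroblast markers had a median log2 fold change of 0.19, and 1 of 13 rose (Scara5, 0.28), also 1 when adjusted over the list alone. The camera adjusted p of fibroblast markers was 0.00248, and adjusted p = 0.729 with an estimated correlation. Epicardial and mesothelial markers had a median of 0.99 with 0 of 10 past the threshold, over all genes or over the list alone (camera adjusted p = 0.0185; adjusted p = 0.739 with an estimated correlation). The epicardial call was lost without replicate 2 of the 4-month females, replicate 1 of the 4-month males, replicate 3 of the 20-month females or replicate 3 of the 20-month males (highest adjusted p = 0.154). In the list of senescence and inflammatory secretion genes 6 of 23 rose and 0 fell, with 11 rising when adjusted over the list alone. These were the chemokine genes Ccl11 (log2 fold change 1.503), Ccl7 (0.99) and Ccl8 (2.02), the metalloproteinase gene Mmp3 (1.10), Igfbp5 (0.41) and Cdkn2a, the locus of p16 and p19 (1.57; 0.145 to 0.621 CPM in females, 0.190 to 0.393 in males). That list had a camera adjusted p of 6.21e-06, and adjusted p = 0.117 with an estimated correlation.

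Immune-cell markers rose in part: 3 of 19 macrophage markers (Cd68 by a log2 fold change of 0.60, Lyve1 by 0.74, Ccr2 by 0.72), 2 of 17 T and NK cell markers (Cd3e by 1.16, Cd3g by 1.54) and 1 of 17 B and plasma cell markers (Ighg2c). Adjusted over the list alone, 9 macrophage, 5 T and NK cell and 2 B and plasma cell markers rose, and 1 of each of the first 2 lists fell. Camera adjusted p was 2.18e-05 for macrophage markers (adjusted p = 0.704 with an estimated correlation) and 0.0179 for T and NK cell markers (adjusted p = 0.739 with an estimated correlation). It was 0.178 for B and plasma cell markers, which did not pass as a list. Neutrophil and monocyte markers had a median log2 fold change of 0.81, with 0 of 11 past the threshold over all genes and 4 rising over the list alone (camera adjusted p = 0.000445; adjusted p = 0.704 with an estimated correlation). The mean log2 CPM of the neutrophil and monocyte list overlapped between 4 and 20 months in females (−2.40 to −1.45 against −1.96 to −1.07). It did not overlap in males (−2.79 to −2.35 against −1.97 to −0.63). Of 33 fatty acid uptake and oxidation genes 2 fell, 4 when adjusted over the list alone: the mitochondrial thioesterase gene Acot2 (−0.59), whose reads may be shared with Acot1, and the malonyl-CoA decarboxylase gene Mlycd (−0.40). The list's camera adjusted p was 5.69e-05, and adjusted p = 0.739 with an estimated correlation. In the interstitial collagen and matrix list only Lum (0.43) and Timp1 (0.69) of 31 rose over all genes, and 2 rose when adjusted over the list alone (camera adjusted p = 0.233). Other genes often followed in ageing or stressed hearts did not pass in edgeR, and these were singled out after their values were seen. The collagen genes Col1a1 and Col3a1 gave log2 fold changes of −0.13 (adjusted p = 0.648) and −0.19 (adjusted p = 0.448). The natriuretic peptide gene Nppb gave −0.13 (adjusted p = 0.908), the beta myosin heavy chain gene Myh7 0.15 (adjusted p = 0.528) and the p21 gene Cdkn1a −0.07 (adjusted p = 0.942). With the clock score as a covariate these 5 had the opposite sign, again without passing. Of the genes named for age averaged over sexes, some passed in at most 6 of 12 leave-one-out fits: Acot2 and Tox3 in 6, Mlycd in 5, Scara5 in 4, Ccr2 and Lum in 3 and Timp1 in 1. These counts do not cover Ccl8, Igfbp5 and Arntl. The T and NK cell call was lost without replicate 2 of the 4-month males, replicate 2 of the 20-month females or replicate 3 of the 20-month males (highest adjusted p = 0.105).

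Clock genes moved in opposite arms with age. Of 19 members 7 rose and 3 fell, and 10 and 3 did so when adjusted over the list alone. Ciart, a repressor of the clock, rose by a log2 fold change of 1.16, Per2 by 1.36 and the output factor gene Hlf by 0.71, while Npas2 and Arntl, the activator genes, fell by 0.93 and 1.05 on the log2 scale. The camera adjusted p of the list was 0.00168, and adjusted p = 0.279 with an estimated correlation. Markers of atrial muscle, the other chamber type that a heart sample can hold, had a median log2 fold change of 1.56 with 0 of 12 past the threshold, over all genes or over the list alone (camera adjusted p = 0.00168; adjusted p = 0.729 with an estimated correlation). Myl7 and Sln of that list gave 2.19 (adjusted p = 0.529 in edgeR) and 2.82 (adjusted p = 0.373).

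In all, 719 of 24873 genes passed an adjusted p of 0.05 in edgeR for age averaged over sexes, 563 higher and 156 lower at 20 months. Over all genes tested, 1.84% had no overlap between the ages, where chance gives 0.216%. The DESeq2 Wald test called 1554. The edgeR count was 275 with the atrial score and 41 with the clock score as a covariate, and 457 without the 2 male libraries low in atrial transcripts. It was 434, 471 and 439 without female replicate 3 of 4 months, male replicate 1 of 4 months and male replicate 2 of 20 months.

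Within females, 375 genes differed between the ages, 266 higher and 109 lower at 20 months. The largest named rises were the receptor gene Gpr158 (log2 fold change 5.30 ± 0.95, SE), Snhg11 (3.65 ± 0.49), Kcnk1 (3.29 ± 0.41), the kinase gene Pak5 (3.22 ± 0.48), Prom2 (2.99), Vgll2 (2.79), Ccl8 (2.77), Scart1 (2.69), Ano5 (2.61), Cdh22 (2.50) and Ighg2c (2.47). The largest named falls were Ddc (−2.19 ± 0.41), the olfactory-type receptor gene Olfr78 (−1.28), Cttnbp2 (−1.19), the fibrillin gene Fbn2 (−1.17), Rbfaos (−1.17), Ephx3 (−1.02), Syt15 (−1.02), Acot2 (−0.95), Cd72 (−0.94), Igf2bp2 (−0.91), Grip2 (−0.86) and Pbld1 (−0.82). Rbfaos carries an antisense-type name, and its reads cannot be told from those of an overlapping gene. Acot2 went from 118 ± 12.3 to 61.2 ± 11.8 CPM (SD, n = 3).

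Of the fixed lists, complement had 4 of 16 rising in females (C1s1 by 0.61, Cfb by 1.45, C1ra by 0.58, C3 by 0.95) and 8 when adjusted over the list alone (camera adjusted p = 5.51e-07; adjusted p = 0.664 with an estimated correlation). Fibroblast markers had a camera adjusted p of 0.0511 in females. Fatty acid uptake and oxidation had 3 of 33 falling, Acot2, Mlycd (−0.62) and the transporter gene Slc27a1 (−0.61), and 8 over the list alone (camera adjusted p = 0.000141; adjusted p = 0.805 with an estimated correlation). Of 23 cardiac ion channel and gap junction genes, 3 rose, among them the sodium channel subunit gene Scn4b (1.15) and the potassium channel gene Kcnq1 (0.44), and 4 over the list alone (camera adjusted p = 0.0436; adjusted p = 0.805 with an estimated correlation). That call was lost in 6 of the 12 leave-one-out fits: without replicates 1 or 3 of the 4-month females, 2 or 3 of the 4-month males, and 1 or 2 of the 20-month females (highest adjusted p = 0.369). Hexokinase genes Hk1 (0.47) and Hk2 (0.46) rose among 24 glycolysis genes, 5 of which rose over the list alone (camera adjusted p = 0.000141; adjusted p = 0.664 with an estimated correlation). Calcium handling genes had a median of 0.13 with 0 of 17 past the threshold, over all genes or over the list alone (camera adjusted p = 0.0247; adjusted p = 0.805 with an estimated correlation). The calcium handling call in females was lost without replicate 1 of the 4-month females or replicates 1 or 2 of the 20-month females (highest adjusted p = 0.179). This list shares Sln with the atrial list. Its mean log2 CPM was 7.62 to 7.87 in the 4-month females, and 7.72 and 7.67 in the 2 male libraries low in atrial transcripts. In the other libraries it was at least 8.025. No list test was run with the atrial score, so calcium handling cannot be told apart here from atrial content. Of the genes named for females, Vgll2 and Mlycd passed in 6 of 12 leave-one-out fits, Ccl8, Ephx3, Hk2 and Rbfaos in 3 and Kcnq1 in 2.

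Atrial markers had a median log2 fold change of 2.66 in females (0 of 12 past the threshold, 0 over the list alone; camera adjusted p = 0.000666; adjusted p = 0.805 with an estimated correlation). Myl7, an atrial myosin light chain gene, stood at 5.44 ± 5.10 CPM at 4 months and 73.2 ± 50.7 at 20 months (SD, n = 3), a log2 fold change of 3.75 ± 2.06 (SE, adjusted p = 0.432 in edgeR), and Myl4 gave 3.32 ± 1.73 (adjusted p = 0.404). Sln gave 4.76 (adjusted p = 0.310). The DESeq2 Wald test called 1435 genes for age in females, 846 higher and 589 lower at 20 months. In the female age comparison the edgeR count of 375 fell to 209 in a fit of the 6 female libraries, 83 with the atrial score and 64 with the clock score. In females the atrial score ran from −3.725 to −0.935 at 4 months and from 1.508 to 3.955 at 20 months. Without overlap between the ages, that fit has little to separate the score from age in females. The count fell to 168, 236 and 155 without replicates 1, 2 and 3 of the 4-month females and to 206 without replicate 2 of the 20-month females.

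Within males, 208 genes differed between the ages, 173 higher and 35 lower at 20 months. Kcnk1 rose by a log2 fold change of 3.69 ± 0.40 (SE), Cyp2b10 by 3.45 ± 0.41, Scart1 by 2.82 ± 0.26, Snhg11 by 2.81 ± 0.46, Klk1b26 by 2.54, Dlgap1 by 2.39, Ryr1 by 2.23, Lypd6 by 2.12, the endothelin gene Edn3 by 2.11, Cdh22 by 1.93 and Vwc2 by 1.92. Ddc fell by 2.34 on the log2 scale, Fam124b by 2.25, Arntl by 1.54, Tmem35a by 1.24, Asxl3 by 1.23, Hrk by 1.17, Npas2 by 1.16, Plekhh1 by 1.14, Fbn2 by 1.10, the apelin receptor gene Aplnr by 1.05, Samd5 by 0.97 and the metalloproteinase gene Adamts4 by 0.92. Aplnr went from 54.5 ± 4.27 to 26.3 ± 4.63 CPM (SD, n = 3).

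Among male lists, complement had 3 of 16 rising (C1s1 by 0.71, C1ra by 0.56, Cfb by 0.86) and 9 over the list alone (camera adjusted p = 4.27e-10; adjusted p = 0.546 with an estimated correlation). Fibroblast markers had a median of 0.18 in males, with 0 of 13 past the threshold over all genes or over the list alone (camera adjusted p = 0.0131; adjusted p = 0.906 with an estimated correlation). That call was lost without replicate 1 of the 4-month males or replicate 2 of the 20-month males (highest adjusted p = 0.318). Senescence and inflammatory secretion had 2 of 23 rising, Mmp3 (1.48) and Ccl11 (1.55), and over the list alone 7 rose and 1 fell (camera adjusted p = 7.95e-05; adjusted p = 0.231 with an estimated correlation). Neutrophil and monocyte markers had a median log2 fold change of 1.44, with 0 of 11 past the threshold over all genes and 8 rising over the list alone (camera adjusted p = 2.28e-06; adjusted p = 0.546 with an estimated correlation). The clock list had 2 rising and 3 falling of 19, among them Ciart (1.29), Per2 (1.67), Arntl and Npas2, with 8 rising and 3 falling over the list alone (camera adjusted p = 0.0481; adjusted p = 0.849 with an estimated correlation). Cardiac ion channel and gap junction genes were lower at 20 months in males by the camera test, with a median of −0.14, 0 of 23 past the threshold over all genes, and 1 rising and 2 falling over the list alone (camera adjusted p = 0.00232; adjusted p = 0.906 with an estimated correlation). Calcium handling genes had a median of −0.08 with 0 of 17 past it, over all genes or over the list alone (camera adjusted p = 0.0195; adjusted p = 0.906 with an estimated correlation). That call was lost without replicate 1 of the 4-month males or replicate 1 of the 20-month males (highest adjusted p = 0.0922), the male libraries low in atrial transcripts. The difference between the sexes in the age effect had a camera adjusted p of 0.000136 for ion channel and 0.000652 for calcium handling genes (adjusted p = 0.990 with an estimated correlation for each). The clock call in males was lost in 6 of 12 leave-one-out fits: without replicate 1 of the 4-month females, replicates 2 or 3 of the 4-month males, replicate 2 of the 20-month females, and replicates 2 or 3 of the 20-month males (highest adjusted p = 0.205). Myl7 ran from 0.172 to 67.3 CPM within the 4-month males and from 0.490 to 107 within the 20-month males (log2 fold change 0.63 ± 1.84, SE, adjusted p = 0.970 in edgeR), and Myl4 gave 0.79 (adjusted p = 0.951). Without replicate 3 of the 20-month males these were −0.57 for Myl7 and −0.24 for Myl4. Of the genes named for males, Ddc and Samd5 passed in 6 of 12 leave-one-out fits, Aplnr, Asxl3, Hrk and Lypd6 in 4, and Cfb and Tmem35a in 3. In males 645 genes passed the DESeq2 Wald test for age. In edgeR the male count of 208 became 104 in a fit of the 6 male libraries, 18 with the clock score and 64 without the 2 libraries low in atrial transcripts. It was 78, 92 and 108 without replicates 1, 2 and 3 of the 4-month males and 121, 112 and 85 without those of the 20-month males.

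The age by sex interaction asks whether age acted differently in the sexes, and 2 genes passed it, Tfrc and Cpxm2. Tfrc (ENSMUSG00000022797.17), the transferrin receptor gene, went from 31.0 ± 0.183 to 62.3 ± 4.31 CPM in females and from 87.4 ± 23.6 to 50.8 ± 4.42 CPM in males (SD, n = 3). Its age effect was 1.01 ± 0.15 in females (SE, adjusted p = 0.00555) and −0.78 ± 0.14 in males (adjusted p = 0.0297 in edgeR; past the threshold in 6 of 12 leave-one-out fits), a difference of −1.79 ± 0.21 (adjusted p = 0.0217). Cpxm2 (ENSMUSG00000030862.14), which encodes a carboxypeptidase-like protein, went from 16.6 ± 2.09 to 58.9 ± 6.08 CPM in females and from 29.5 ± 3.87 to 41.1 ± 4.59 CPM in males (SD, n = 3). Its difference was −1.35 ± 0.17 (SE, adjusted p = 0.0217 in edgeR). In edgeR 2471 genes had an unadjusted p under 0.05. The count was 261 by the DESeq2 Wald test. It was 0 in edgeR without replicate 3 of the 4-month females, replicate 2 of the 20-month females or replicate 2 of the 20-month males, with 2255, 1953 and 2405 genes at an unadjusted p under 0.05. It was 1 without replicate 1 of the 4-month females, replicate 3 of the 4-month males or replicate 1 of the 20-month males, 10 without replicate 2 of the 4-month females, and 6 and 13 without replicates 1 and 3 of the 20-month females. Without replicate 1 of the 4-month females, the 1 gene was neither Tfrc nor Cpxm2. Tfrc stayed past the threshold in 7 of the 12 leave-one-out fits and Cpxm2 in 5, and the log2 difference stayed negative in all 12 for each. Without both male libraries low in atrial transcripts the adjusted p was 0.158 for Tfrc and 0.121 for Cpxm2, the highest of any alternative.

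**Figure D2:**
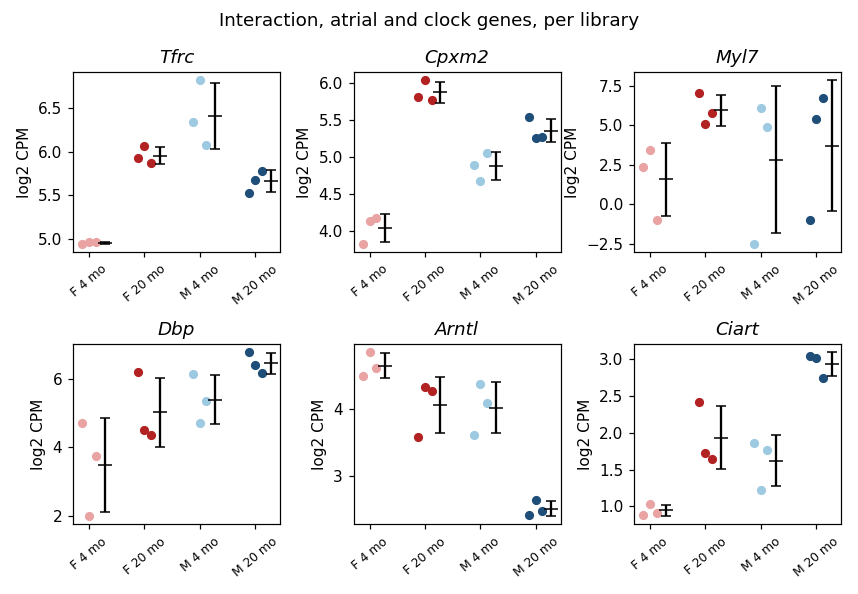
Log2 CPM of Tfrc, Cpxm2, Myl7, Dbp, Arntl and Ciart (y axis) in the 12 libraries, grouped by sex and age (x axis; F, females; M, males). Points are libraries, and the bars beside them give the mean and SD of 3. Tfrc CPM was higher at 20 than at 4 months in females (62.3 against 31.0) and lower in males (50.8 against 87.4), and Myl7 ranged from 0.172 to 130 CPM between libraries.

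Across the 24873 genes, the age effects of the sexes had Pearson r = 0.171 and Spearman rho = 0.140 (genes are not independent replicates). Of the genes that rose, 83 were shared by females and males where independent lists would share 1.85, and of those that fell, 6 were shared against 0.153. Only Tfrc passed in both sexes with opposite signs. Among the 375 genes that passed in females, 303 (80.8%) had the same sign in males, and of the 208 that passed in males, 193 (92.8%) had the same sign in females. No library enters both of these contrasts, but both were tested with a spread per gene estimated from all 12 libraries. The overlaps given for independent lists are therefore only a guide.

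The next comparison asks what differed between males and females with the ages weighed equally. Beside the Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty, the complement gene C7 was higher in males, by a log2 fold change of 2.36 ± 0.18 (SE). It stood at 2.90 ± 0.322 and 4.00 ± 0.935 CPM in females of 4 and 20 months and 13.6 ± 4.78 and 22.6 ± 0.437 in males (SD, n = 3). The complement gene C1s1 went the other way, with a log2 fold change of −0.21 (adjusted p = 0.0397 in edgeR). Also higher in males were the aminopeptidase gene Lvrn (log2 fold change 2.16), Smim41 (1.24), Hsd11b1, which encodes the enzyme that regenerates active glucocorticoid (1.13), Eya2 (0.99), the neuropeptide gene Nmb (0.82), Coq10b (0.76) and Lgi1 (0.69). Lower in males, beside Xist (−9.04 ± 0.46), were the pigment genes Slc24a5 (−1.19) and Dct (−1.09), Lrrc55 (−1.10), the calcium-activated potassium channel gene Kcnn3 (−0.77), Gprasp2 (−0.75), Sema3d (−0.75), Scml4 (−0.74) and Igsf10 (−0.73). Also lower were X-linked Kdm6a (−0.83), Pbdc1 (−0.73) and Kdm5c (−0.71). Xist overlaps its antisense partner Tsix, whose reads cannot be separated here. Tsix gave 1.68 (adjusted p = 0.129 in edgeR) and Utp14a −0.25 (adjusted p = 0.0687). Ddx3x (−0.62), Eif2s3x (−0.61) and 5530601H04Rik (−0.67) were lower in males too, so that 7 of 9 X-inactivation and escape genes were lower. Adjusted over the list alone, 8 were lower and 1 higher (camera adjusted p = 4.06e-16, and adjusted p = 0.00255 with an estimated correlation).

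Clock genes differed between sexes as they did between ages: 7 of 19 were higher and 3 lower in males, and 12 and 4 when adjusted over the list alone. Hlf (0.87), Tef (0.90) and Usp2 (0.62) were higher and Npas2 (−1.02) and Arntl (−1.09) lower (camera adjusted p = 1.15e-05; adjusted p = 0.0671 with an estimated correlation). Arntl averaged 25.1 CPM in 4-month females, 17.0 in 20-month females, 16.5 in 4-month males and 5.70 in 20-month males. Interferon-stimulated genes were lower in males with a median log2 fold change of −0.44, where 1 of 33 (Oas1a, −0.56) passed over all genes and 20 over the list alone (camera adjusted p = 1.55e-12; adjusted p = 0.540 with an estimated correlation). The mean log2 CPM of that list was 4.005 in replicate 2 of the 20-month females and at most 3.52 in the other 11 libraries, and without that replicate the camera adjusted p was 4.12e-09. T and NK cell markers were lower in males too, with a median log2 fold change of −0.54, 1 of 17 lower (Ccl5, −1.05) and 9 over the list alone (camera adjusted p = 0.000106; adjusted p = 0.537 with an estimated correlation). Of 31 interstitial collagen and matrix genes, Lum (−0.54) and Col14a1 (−1.17) were lower in males, and 17 over the list alone (camera adjusted p = 6.21e-08; adjusted p = 0.547 with an estimated correlation). The mean log2 CPM of the matrix list was lowest in the 2 male libraries low in atrial transcripts, at 4.61 in replicate 1 of 4 months and 4.85 in replicate 1 of 20 months, against at least 5.05 elsewhere. Replicate 3 of the 4-month females was as low in atrial transcripts (Myl7 at 0.497 CPM). Its matrix mean was 5.21, so the matrix list did not go with atrial transcripts there. Markers of other cell types were also lower in males by the camera test. Fibroblast markers had 1 of 13 lower (Islr, −0.44), and over the list alone 4 lower and 1 higher (camera adjusted p = 0.013; adjusted p = 0.576 with an estimated correlation). That call was lost without replicate 1 of the 4-month females, replicate 1 of the 4-month males or replicate 3 of the 20-month females (highest adjusted p = 0.0904). Adipocyte markers had a median log2 fold change of −0.46, with 0 of 16 lower over all genes and 1 over the list alone (camera adjusted p = 0.00544; adjusted p = 0.576 with an estimated correlation). Their mean log2 CPM was −1.71 and −1.47 in the same 2 male libraries and ran from −0.48 to 1.535 in the other 10, where replicate 3 of the 20-month males was highest. It was 0.594 in replicate 3 of the 4-month females, the female library low in atrial transcripts. Epicardial and mesothelial markers had a median of −0.31, with 0 of 10 lower over all genes and 1 over the list alone (camera adjusted p = 0.012; adjusted p = 0.576 with an estimated correlation). The epicardial call was lost without replicate 2 of the 4-month males or replicate 2 of the 20-month males (highest adjusted p = 0.167). Of 17 proliferation genes 0 passed over all genes and 10 were lower over the list alone (camera adjusted p = 6.05e-07; adjusted p = 0.537 with an estimated correlation).

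The 13 mitochondrially encoded genes had a median log2 fold change of 0.21, with 0 past the threshold over all genes and 12 over the list alone (camera adjusted p = 2.10e-08; adjusted p = 0.537 with an estimated correlation). Among 19 genes of branched-chain amino acid breakdown Bckdha (0.29) was higher, and 7 over the list alone (camera adjusted p = 2.27e-08; adjusted p = 0.540 with an estimated correlation). Hadh (0.34) was higher among 33 fatty acid genes, of which 11 were higher and 1 lower over the list alone (camera adjusted p = 3.35e-05; adjusted p = 0.576 with an estimated correlation). In all, 358 genes passed in edgeR, 220 higher and 138 lower in males, of which 329 were autosomal, 22 X-linked and 6 Y-linked. Of the genes named for sex averaged over ages, Bckdha, Hadh and Ccl5 passed in 5 of 12 leave-one-out fits, Oas1a and C1s1 in 3, and Col14a1, Nmb and Sema3d in 2. These counts do not cover Arntl. Over all genes tested, 1.31% had no overlap between the sexes, where chance gives 0.216%. The DESeq2 Wald test called 1413. The edgeR count was 10 with the clock score and 105 without the 2 male libraries low in atrial transcripts. Without replicates 1 and 3 of the 4-month females it was 190 and 154. It was 149 and 179 without replicates 1 and 3 of the 4-month males, and 171 without replicate 3 of the 20-month females. It was 208, 152 and 219 without replicates 1, 2 and 3 of the 20-month males.

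At 4 months, 456 genes differed between the sexes, 334 higher and 122 lower in males. Beside the Y-linked genes, C7 (log2 fold change 2.23 ± 0.25, SE), Lvrn (2.20), the adenylyl cyclase gene Adcy1 (1.99), Cnmd (1.78), Smim41 (1.59), Ccl11 (1.59), Tfrc (1.49 ± 0.15) and Hsd11b1 (1.26) were higher in males. Beside Xist, Dct (−1.42), Slc24a5 (−1.15), Cd72 (−1.09), Pla2g4b (−1.09), AI838599 (−1.08), the keratin gene Krt80 (−1.04), Pbld1 (−0.98), Piwil2 (−0.97), Clec18a (−0.94), Tcf23 (−0.92) and the X-inactivation centre RNA Ftx (−0.91) were lower. Cardiac ion channel genes had 2 of 23 higher in males, among them the connexin gene Gja1 (0.48), with 6 higher and 1 lower over the list alone (camera adjusted p = 2.12e-05; adjusted p = 0.584 with an estimated correlation). The clock list had 4 of 19 higher, Hlf (0.99), Tef (0.997), Usp2 (0.71) and Nr1d2 (0.56), and over the list alone 8 higher and 2 lower (camera adjusted p = 8.71e-05; adjusted p = 0.115 with an estimated correlation). Atrial markers had a median of 1.69 (camera adjusted p = 0.228), with Myl7 at 2.58 (adjusted p = 0.579 in edgeR), Myl4 at 2.20 (adjusted p = 0.573) and Sln at 3.54 (adjusted p = 0.411). Some genes named for 4 months passed in at most 6 of 12 leave-one-out fits: Piwil2 in 6, AI838599 and Slc24a5 in 5, and Gja1 and Tcf23 in 4. At 4 months 1623 genes passed the DESeq2 Wald test. In edgeR the count at 4 months was 16 with the clock score and 86 without the 2 male libraries low in atrial transcripts. It was 123 and 121 without replicates 1 and 3 of the 4-month females, 114, 176 and 126 without replicates 1, 2 and 3 of the 4-month males, and 263 and 293 without replicates 2 and 3 of the 20-month males.

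At 20 months, 32 genes differed between the sexes, 16 in each direction, 5 of them Y-linked, 6 X-linked and 21 autosomal. Autosomal genes higher in males were C7 (log2 fold change 2.50 ± 0.25, SE), Cnmd (1.72), Ccl11 (1.67), Hsd11b1 (0.99), the protease inhibitor gene Serpina3n (0.95), the enkephalin precursor gene Penk (0.88), Coq10b (0.71) and Ogdhl (0.55). Lower in males were Fam124b (−2.35 ± 0.19), Arntl (−1.58), Lrrc55 (−1.41), Npas2 (−1.24), Adamts4 (−1.13), Kcnn3 (−0.88), the monocarboxylate transporter gene Slc16a7 (−0.86) and Smoc2 (−0.85), beside Xist, Kdm6a (−0.85), Kdm5c (−0.80) and Pbdc1 (−0.73). Smoc2, a matricellular gene, stood at 95.8 ± 3.85 CPM in females and 53.0 ± 3.86 in males (SD, n = 3, adjusted p = 0.000106 in edgeR). Arntl passed at 20 months in 6 of 12 leave-one-out fits, Cnmd and Penk in 3 and Kcnn3 in 1. The DESeq2 Wald test called 261 genes at 20 months, 101 higher and 160 lower in males. The edgeR count at 20 months was 7 with the clock score, 21 with the atrial score and 21 without the 2 male libraries low in atrial transcripts, and 20 without replicate 2 of the 20-month females or replicate 1 of the 20-month males.

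Over 23936 autosomal genes the sex effects at the 2 ages had Pearson r = 0.0533 and Spearman rho = 0.0601 across genes, which are not independent replicates. Without replicate 3 of the 20-month females r was −0.0014, and over genes with a mean CPM of at least 10 it was 0.192. Of the autosomal genes higher in males, 7 were shared by the ages where independent lists would share 0.148, and of those lower, 3 were shared against 0.0464, with 0 of opposite sign. Both contrasts again use the spread per gene from all 12 libraries, so these overlaps for independent lists are only a guide. Among the 434 autosomal genes that passed at 4 months, 328 (75.6%) had the same sign at 20 months. Whether the sex effect differed between the ages is the interaction test, which 2 genes passed, so the larger count at 4 months is not shown to be a difference between the ages for the other genes.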

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

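The tests of the atrial and clock patterns were chosen after those patterns were seen. The tests of called genes against a score, and their bounds, were set before their results were seen, but how 2 of those results are read was settled afterwards, as stated with them. A test of the difference itself set Tfrc and Cpxm2 apart, with an age effect in males minus that in females of −1.79 for Tfrc and −1.35 for Cpxm2 (log2, edgeR adjusted p = 0.0217 for each). Of 100 splits that reassigned age within each sex, 15 gave at least 2 genes and the highest other count was 719. These splits leave the age effect in the data, and swapping the ages in one of the sexes turns it into an interaction, so they do not decide whether chance gives the count of 2.

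The camera test of the same difference passed for 11 gene lists with the preset correlation, and for none with an estimated one (adjusted p = 0.990 for each). The median differences, males minus females, were −2.18 for atrial markers, 1.21 for neutrophil and monocyte markers, −1.005 for MHC class II, −0.45 for MHC class I and immunoproteasome, −0.37 for cardiac ion channels and gap junctions, 0.26 for smooth muscle and pericyte markers, 0.25 for endothelial markers, −0.23 for calcium handling, −0.19 for glycolysis, −0.18 for branched-chain amino acid breakdown and −0.078 for nuclear oxidative phosphorylation. With each library left out in turn, the call was kept in all 12 fits for calcium handling, ion channels and glycolysis, in 11 for endothelial and neutrophil markers, in 9 for smooth muscle markers and branched-chain amino acid breakdown, in 8 for MHC class II, in 6 for MHC class I and for nuclear oxidative phosphorylation, and in 4 for atrial markers. Without replicate 2 of the 20-month females the camera adjusted p for the difference was 0.276 for MHC class II and 0.934 for MHC class I and immunoproteasome, against 0.0219 and 0.042 with it. The calcium handling list holds the atrial gene Sln, and its mean was low in the libraries low in atrial transcripts. Its difference is therefore not set apart from that of the atrial markers.

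The first pattern is that atrial transcripts differed between libraries, with Myl7 from 0.172 to 130 CPM. Age as the sole source is argued against, since in males the atrial score differed between the ages by 1.23 while its SD within the male groups was 3.70 and 3.48. Different shares of atrial tissue in the hearts sampled remain a candidate explanation: within groups the other 11 atrial genes had a median correlation with Myl7 of 0.943, and 8 of the 11 were at 0.5 or above. In females the atrial score was 4.87 higher at 20 months, with an SD of 1.40 at 4 months and 1.30 at 20 months. An effect of age within females stays open. Averaged over sexes the atrial score was 3.05 higher at 20 months (exact permutation p = 0.1, two-sided over 400 arrangements), and the atrial list rose in females by the camera test (adjusted p = 0.000666) but not with an estimated correlation (adjusted p = 0.805).

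The second pattern is that clock genes differed between groups. The clock score was higher at 20 months by 4.60 and in males by 4.94 (exact permutation p = 0.005 for each, two-sided over 400 arrangements, the smallest they can give), and 88.4% of its variance lay between groups. Over the 19 clock genes the age and sex effects had a rank correlation of 0.882, and 18 had the same sign in both. The score holds 74.1% of the list's variance and was higher in both comparisons. The correlation thus largely follows from the score and adds no separate support. Collection of the groups at different times of day could give this, and so could a shift of phase with age and sex; the labels used here give no time of day, so these cannot be told apart.

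The third pattern is how far the genes past the threshold in a comparison of a pair of groups follow either score, tested in the 6 libraries that the comparison did not use. Of the female age genes 58.4% went with the atrial score within males in the direction of the call (permutation p = 0.167 over 36 exact permutations) and 44.5% with the clock score (exact p = 0.833). Of the male age genes 49.5% went with the atrial score within females (exact p = 0.556) and 54.7% with the clock score (exact p = 0.278). Of the sex genes at 4 months 53.5% went with the atrial score within the 20-month groups (exact p = 0.417) and 57.7% with the clock score (exact p = 0.444). The bound set beforehand against an explanation was a share of at most 50%, which 44.5% and 49.5% meet. Both lay within the spread of the 36 permutations, and only after they were seen was it decided that a share must also lie below that spread to count against the explanation. On that reading none of the 6 shares decides, and what part of the called genes atrial content or clock phase might carry cannot be told apart from age or sex with 6 libraries.

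For the counts of genes, 1 of 100 splits, the real grouping, gave 719 genes for age averaged over sexes against at most 35 in the others. Likewise 1 of 100 gave 358 for sex averaged over ages against at most 166. Fewer than 5 in 100 splits, the bound set beforehand, thus reached either count, which argues against chance as its source. The 358 include 6 Y-linked genes and Xist, which mark sex itself. Such splits do not part age or sex from other differences between the groups, such as the clock score. The comparisons of 3 against 3 allow 10 splits, too few for a share under 0.05. Each had 1 split as large as the real one, itself: 375 in females against at most 2, 208 in males against at most 0, 456 at 4 months against at most 0 and 32 at 20 months against at most 0.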

How the results depend on the processing

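Alternatives with a covariate score, counts divided by 4, both male libraries low in atrial transcripts left out, or a library left out of the correlations were chosen after seeing the data. Counts below are in the order age averaged, age in females, age in males, sex averaged, sex at 4 months, sex at 20 months and interaction, whose main counts were 719, 375, 208, 358, 456, 32 and 2. The DESeq2 Wald test gave 1554, 1435, 645, 1413, 1623, 261 and 261; in simulated data it called 37 to 60 unchanged genes per contrast against 4 to 18 for edgeR. The clock score as a covariate gave 41, 64, 18, 10, 16, 7 and 6, and 88.4% of that score lay between groups, so the fit has little left to separate it from them. The atrial score gave 275 for age averaged, 83 for age in females and 21 for sex at 20 months. In females that score did not overlap between the ages, so the fit has little to separate it from age there. Leaving out both male libraries low in atrial transcripts gave 457 for age averaged, 64 for age in males, 105 for sex averaged, 86 for sex at 4 months, 21 for sex at 20 months and 0 for the interaction (2142 genes at an unadjusted p under 0.05), with fewer samples. Fits of the 6 libraries compared gave 209 in females and 104 in males, with fewer degrees of freedom. The interaction also moved to 11 without a filter, 4 with limma-voom, 4 with counts divided by 4 and 1 with the replicate block; the cause was not tested. Leaving out each library gave 434 to 690, 155 to 419, 78 to 220, 149 to 421, 114 to 538, 20 to 40 and 0 to 13 genes. Keeping annotated genes only removed nothing, and DESeq2 size factors moved no count by over 1.5 times.

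The 117 list calls became 5 with an estimated correlation, 123 with the replicate block and 104 to 124 with a library left out. The correlation of the age effects was 0.171, 0.252 at a mean CPM of at least 10 and 0.0930 to 0.191 with a library left out. That of the sex effects was 0.0533, 0.192 at a mean CPM of at least 10 (the cause was not tested) and −0.0014 to 0.0725 with a library left out, below 0 without replicate 3 of the 20-month females. The labels repeat the replicate numbers 1 to 3. Same-numbered libraries had deviations correlated by 0.009 on average (−0.029 to 0.094), against −0.0045 for other numbers. The highest value, 0.094, was between replicate 1 of the 4-month males and replicate 1 of the 20-month males. Of 12 libraries, 5 matched their own number best. Taken over all genes, these values give no clear sign that the numbers pair the libraries, but so weak a check cannot rule pairing out. In each of the 4 groups, however, replicate 1 had the highest clock score, the highest Dbp and the lowest Arntl. Its clock score was −4.07 in 4-month females, 1.85 in 4-month males, 2.37 in 20-month females and 4.97 in 20-month males. The numbers may thus carry a shared difference in clock genes. This was seen afterwards, and its source was not tested. With the replicate block the counts were 703, 398, 222, 323, 371, 40 and 1.

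Of the 24 genes named by rank for age averaged over sexes, 23 stayed past the threshold in every leave-one-out fit and 24 under every other alternative fixed beforehand that tested them. For age in females these were 12 and 18, for age in males 9 and 11, for sex averaged 22 and 23, for sex at 4 months 13 and 22, and for sex at 20 months 13 and 13. Of the 2 interaction genes, 0 and 1 did so. Nrk, Prom2, Vgll2, Gpr158 and Pak5 were not tested under the CPM filter, which removed them. With the atrial score 21, 12, 22, 24, 21 and 16 of each 24 passed, and with the clock score 3, 4, 2, 8, 7 and 6, where all 24 kept their sign. Values that changed sign were of genes that did not pass or, for Utp14a, of a label check. With the atrial score, built from a list that holds them, Myl7 gave −1.11 for age averaged, −1.58 in females, −0.63 in males and −0.96 for sex at 4 months. Myl4 gave −0.70 in females, −0.26 in males and −0.26 for sex at 4 months, and Sln −0.39, −0.43 in females and −0.14 for sex at 4 months. With the clock score, built from a list that holds Dbp, Dbp gave −1.20 for age and −1 for sex. Age effects with the clock score were 1.06 for Cdkn1a, 1.20 for Nppb, 0.13 for Col1a1, 0.026 for Col3a1 and −0.20 for Myh7, and Utp14a gave 0.06 for sex at 4 months; the cause was not tested. With a library left out, Myl7 in males ran from −0.57 to 1.75, Myl4 in males from −0.24 to 1.93, Cdkn1a for age averaged from −0.20 to 0.054 and Nppb from −0.32 to 0.019. At this depth and n the interaction test recovered 19.4% of simulated 1.5-fold differences in genes with a mean CPM of at least 1. Most differences of that size were therefore not detectable.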

Other observations

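Replicate 2 of the 20-month females stood apart in interferon-gamma-type genes. The GTPase gene Igtp was at 131 CPM there and between 13.0 and 25.5 CPM in the other 11 libraries. The MHC class II gene H2-Aa was at 131 CPM against 33.0 to 68.9. These genes were picked after their values were seen, and the comparison is a description of that library. Without it, the rise of the MHC class II list with age in females had a camera adjusted p of 0.893, against 0.0322 with it. The call was also lost without replicate 3 of the 4-month females. Its median log2 fold change with all libraries was 0.77, with 0 of 8 members past the threshold over all genes or over the list alone, and adjusted p = 0.805 with an estimated correlation.

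Neutrophil genes S100a8 and S100a9 were uneven among the 20-month males, at 1.92 and 2.91 CPM in replicate 1, 0.534 and 0.730 in replicate 2 and 1.05 and 1.73 in replicate 3. In the other 9 libraries S100a8 was at 0.785 CPM or below and S100a9 at 1.18 or below. Replicate 1 was the highest of its group for both genes in all 4 groups, though barely so for S100a9 in 4-month males (0.4777 against 0.4769 CPM). The mean of the neutrophil and monocyte list was also highest in replicate 1 of each group, as was the clock score. The cause was not tested. For age averaged over sexes, 1 of 16 endothelial markers fell, Tie1 (−0.24), and 5 when adjusted over the list alone. The camera adjusted p of that list was 0.0068, and adjusted p = 0.739 with an estimated correlation. It was 0.000218 in females, with 1 of 16 falling (Tie1, −0.37) and 5 over the list alone (adjusted p = 0.805 with an estimated correlation), and 0.929 in males. The difference between the sexes had a camera adjusted p of 0.0033 (adjusted p = 0.990 with an estimated correlation), lost without replicate 1 of the 20-month females (0.0575). Tie1 passed in 2 of 12 leave-one-out fits for age averaged and in 2 in females, and Sod3 below in 4 for age averaged. Smooth muscle and pericyte markers had a median of −0.11 for age averaged, with 0 of 15 past the threshold over all genes or over the list alone (camera adjusted p = 0.0185; adjusted p = 0.729 with an estimated correlation). That call was lost without replicate 3 of the 4-month females or replicate 1 of the 20-month females (highest adjusted p = 0.112). In females their median was −0.25, with 0 of 15 falling over all genes and 6 over the list alone (camera adjusted p = 0.0017; adjusted p = 0.664 with an estimated correlation). The camera adjusted p of smooth muscle and pericyte markers was 0.935 in males and 0.0168 for the difference between the sexes (adjusted p = 0.990 with an estimated correlation). That difference was lost without replicate 3 of the 4-month females, replicate 1 of the 20-month females or replicate 2 of the 20-month males (highest adjusted p = 0.111). Of 24 glycolysis genes Pfkfb3 rose (0.41), 1 gene over the list alone (camera adjusted p = 0.00372; adjusted p = 0.729 with an estimated correlation). Of 23 antioxidant genes Gsta4 (0.39) and Sod3 (0.24) rose, and 4 over the list alone (camera adjusted p = 0.0179; adjusted p = 0.729 with an estimated correlation). The endothelial call was lost without replicate 1 of the 4-month females or replicate 1 of the 20-month females (highest adjusted p = 0.0722). The antioxidant call was lost without replicate 1 of the 4-month females, replicate 2 of the 4-month males or replicate 1 of the 20-month males (highest adjusted p = 0.0965). Cytosolic ribosomal protein genes had a median log2 fold change of 0.09 with 0 of 50 past the threshold, over all genes or over the list alone (camera adjusted p = 0.000178; adjusted p = 0.832 with an estimated correlation).

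Dbp, a clock output gene, was at 26.0 CPM or below in the 4-month females and at 72.5 CPM or above in the 20-month males, with log2 fold changes of 1.19 ± 0.52 for age and 1.43 ± 0.53 for sex (SE) and adjusted p of 0.337 and 0.253 in edgeR.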
